A study of Caenorhabditis elegans with 12 samples.

How the data were processed

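Polysomal and nonpolysomal RNA of wild-type and ife-1(bn127) worms was measured on 12 Affymetrix arrays, 3 per genotype and fraction. Groups were taken from the labels. Per the labels, RNA from gradient fractions was extracted with Trizol, pooled, and labelled with biotin. The deposited intensities are probe set signals on a linear scale, described in the labels as raw signal imported from the Affymetrix files. The software, its version and any scaling between arrays are not given in the sources used here. Array medians lay within 1.17-fold of each other. The authors filtered 22626 probe sets to 13372 on detection, per the file headers. Every retained probe set has at least 2 present calls among the 4 arrays of each set and at least 6 among all 12 arrays. The deposited detection calls could be assigned to groups but not to single arrays. The authors also deposited a mean fold of the polysomal share P/(NP+P) and of the sum NP+P, wild type over ife-1, where P and NP are the polysomal and nonpolysomal signals. Recomputed from the signals, both folds matched within 0.0001 for all 13372 probe sets. In the workbook, 36 other columns of per-sample values were not used.

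After 39 control probe sets were removed, 13333 were tested. Gene names came from the platform annotation, which gives 1 gene for 12616 probe sets, several for 459 and none for 258. Of the first kind, 12595 matched the RefSeq gene table, and together they name 10334 genes. Where a gene has several probe sets, the brightest by mean log2 signal over the arrays was used. Signals below 1 were set to 1, which affected 5 values, and log2 signals were quantile-normalized over the 12 arrays. Quantile normalization removes any overall difference in RNA amount, so all values are relative to the average mRNA of an array. Association is log2(P/NP) in a culture, and combined abundance is log2(P + NP). Since arrays were normalized singly, the sum weights both fractions alike whatever their RNA yield.

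Groups were compared with limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over probe sets and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3. Gene lists were tested with limma's camera at a preset correlation of 0.01, for lists with at least 4 measured genes, adjusted over 24 lists. A probe set without any present call in a group has only a bound there. The bound sets the other group's mean against the higher, on each array, of its own signal and the lowest signal among probe sets called present on all 3 arrays of the group. The number of arrays limits the precision.

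The deposited outline of the procedure states that wild-type and mutant samples were paired in growth sets, and that harvests were separate, so set numbers pair the cultures. Deviations of same-numbered cultures from their genotype's mean correlated at -0.032, -0.0627 and 0.0234 in association and at -0.113, -0.0532 and 0.13 in abundance, across probe sets. Tests were made without this block, and the blocked fit is an alternative. No pair of arrays was a duplicate: correlations within groups ranged from 0.916 to 0.988. The wild-type culture of set 2 correlated at 0.773 and 0.755 in log2 P/NP with the other wild-type cultures, which correlated at 0.858 with each other.

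The groups, tests, gene lists and rule for named genes were fixed before the data were examined. Named were ife-1 and its paralogs; in each direction, the 10 genes with the largest association change, the 8 with the largest abundance change and the 6 with the largest wild-type fraction difference, among those past the threshold and without overlap, filled up with the smallest unadjusted p; up to 4 members per list; all members of the list of reported targets and its comparison list; and the 5 highest and lowest of the authors' share folds. The text names part of these. Alternatives were signals as deposited, median scaling, quantile normalization within fractions, brighter probe sets, an offset of 50, a variance trend, the replicate block, unpaired fractions, other outcome scales, camera with an estimated correlation, fry, and leaving out each set. Scaling on bacterial control probe sets, probe sets present on all 12 arrays and leaving out each single culture were added after the data were seen.

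The scripts were tested on simulated arrays built from the means and spreads of the 13333 probe sets, with 200 changed in each of 5 simulations. For association, 0.6% of 2-fold and 34.8% of 4-fold changes were recovered, and 3.8% of calls were unchanged probe sets. For abundance, 50.2% of 2-fold and 93.4% of 4-fold changes were recovered, and 6.51% of calls were unchanged probe sets. Among 10334 genes, a list of 25 genes shifted by 0.5 was called in 5 of 5 simulations, and 0 unshifted lists were called. Noise was drawn independently for each probe set and array, so simulated list members were uncorrelated. The list result therefore does not cover false calls of lists with correlated members. In the data the estimated correlation in association was 0.37 for major sperm proteins and 0.33 for proteasome genes. The 2 fractions of a simulated culture also shared no variation, so the simulations do not cover the pairing of fractions. In the data, 2730 probe sets had an unadjusted p under 0.05 in limma on the paired ratios. The interaction with no culture block gave 1479. Recovery in the data can therefore differ from the simulated rates, for association and for abundance.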

Results

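The series measured which mRNAs of the nematode Caenorhabditis elegans sediment with polysomes in wild-type worms and in the mutant ife-1(bn127). IFE-1 is a germline isoform of eIF4E, the translation initiation factor that binds the mRNA cap. Mixed-stage worms were grown for a final 3 days at 20 °C, and their lysates were separated on gradients of 10 to 45% sucrose. RNA lighter than 80S was pooled as the nonpolysomal fraction, and RNA heavier than 80S was pooled as the polysomal fraction. Each fraction was measured on an Affymetrix array, in 3 separately harvested cultures per genotype, which gives 12 arrays in 4 groups of 3. Median deposited signals ranged from 367.3 to 428.6 per array, and 13333 probe sets were tested. The number of arrays limits the precision of every value below.

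The first check concerned the mutated gene. The ife-1 probe set gave deposited signals of 3567 to 5997 on the 6 wild-type arrays and of 62.3 to 177.7 on the 6 mutant arrays. It was called present on 3 of 3 arrays in both wild-type groups and on 0 of 3 in both mutant groups. Combined ife-1 signal was therefore at least 38.1-fold lower in the mutant (limma adjusted p = 4.28e-05). Whether this probe set lies inside the region altered by bn127 is not given in the sources used here. Among the other eIF4E isoforms, combined abundance of ife-3 was higher by 1.26 ± 0.18 on the log2 scale (SE, 3 cultures per genotype; adjusted p = 0.00262). That of ife-5 was higher by 0.91 ± 0.17 (adjusted p = 0.00617). The abundance of ife-2 differed by 0.08 ± 0.19 and that of ife-4 by 0.06 ± 0.29, with adjusted p of 0.743 and 0.885. Polysomal shares of ife-4 averaged 73.0% in wild type and 56.3% in the mutant, and those of ife-2 averaged 72.9% and 53.3%. Neither difference in association passed the threshold (adjusted p = 0.0639 and 0.155), and ife-4 was called present on no nonpolysomal wild-type array.

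Polysomal and nonpolysomal RNA were compared within each genotype first. In wild type, 3538 probe sets were relatively richer in polysomes and 3900 in the nonpolysomal fraction. In the mutant these counts were 3032 and 3485. The balance followed the scaling: with signals as deposited the counts were 3713 and 3729 in wild type and 3783 and 2966 in the mutant, and with median scaling they were 3116 and 4446, and 2877 and 4139. In total 5050 probe sets passed in both genotypes, 5005 of them with the same sign. Among the most polysomal wild-type mRNAs were sfrp-1, which encodes a secreted Frizzled-related protein, cdh-4, a cadherin, and cnc-6, an antimicrobial peptide gene. Polysomal shares were 95.9% ± 0.77 for sfrp-1, 92.8% ± 5.34 for cdh-4 and 94.4% ± 2.86 for cnc-6 (SD, n = 3). These mRNAs, with trr-1, gmap-2 and F36G3.2, were called present on none of the nonpolysomal wild-type arrays. Their polysomal signal was at least 17.1-fold higher for sfrp-1, 16.9-fold for trr-1, 15.6-fold for gmap-2, 11.8-fold for cdh-4, 7.68-fold for F36G3.2 and 5.40-fold for cnc-6. At the other end, gpa-9, a G protein alpha subunit gene, had a polysomal share of 8.58% ± 0.65 and was at least 8.80-fold higher in the nonpolysomal fraction. T16H12.2, Y38E10A.14, F22F4.4, ZK858.2 and F55C5.2 had shares of 7.28%, 10.1%, 9.55%, 9.71% and 11.4%. For T16H12.2 and Y38E10A.14 no wild-type polysomal array gave a present call. Their nonpolysomal signal was at least 6.11-fold and 9.36-fold higher. Of 31 meiotic chromosome genes, 25 were significantly nonpolysomal in wild type and 0 polysomal. Of 30 maternal RNA-binding and cell-fate genes, 24 were nonpolysomal and 2 polysomal. Of 23 major sperm protein genes, 21 were polysomal and 0 nonpolysomal. Of 32 proteasome genes, 20 were polysomal and 2 nonpolysomal. Without pairing of the fractions, the totals of 7438 and 6517 calls became 5693 and 4779. Without set 1 they were 4857 and 4018.

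The central comparison asked which mRNAs changed their polysomal content when IFE-1 was missing. Association was the log2 ratio of polysomal to nonpolysomal signal in each culture, given here as ife-1 minus wild type. In all, 4 probe sets were higher and 13 were lower among 13333 (limma, adjusted p under 0.05). The mRNA of iscu-1, which encodes an iron-sulfur cluster scaffold, fell from a polysomal share of 82.2% ± 1.51 in wild type to 45.3% ± 6.21 (SD, n = 3; log2 ratio change -2.49 ± 0.24, SE; adjusted p = 0.0267). The fatty acid elongase mRNA elo-4 fell by 1.97 ± 0.23 in the log2 ratio (SE; adjusted p = 0.0403). The mRNA of sid-3, a tyrosine kinase needed for import of double-stranded RNA, fell from 85.8% ± 1.15 to 66.1% ± 4.23 (adjusted p = 0.0444). Also lower were K06H6.1 (log2 ratio change -1.76), the ligand-gated ion channel gene lgc-21 (-1.58), R12C12.5 (-1.58), the chemoreceptor-family gene srbc-1 (-2.27), and, as upper limits of the size, Y43F8C.13 (-2.44) and F15D4.5 (-1.61). The cytochrome P450 mRNA cyp-35A2 passed as higher, with measured shares of 40.9% ± 2.40 in wild type and 74.3% ± 3.26 in the mutant (adjusted p = 0.0267). ZK1290.11 rose from 30.7% ± 5.96 to 63.5% ± 3.09, and ZK550.6 from 62.7% ± 4.34 to 84.5% ± 1.69. Combined log2 signals of ZK1290.11 were 11.5, 5.52 and 11.2 in wild-type cultures 1 to 3. Its share in wild-type culture 2 thus rests on a far lower signal, although all 12 arrays called it present. The log2 ratio of T12D8.5 rose by 1.73 ± 0.23 (SE). In each of these 13 genes the 3 mutant cultures lay on the same side of all 3 wild-type cultures. The naming rule asked for this, so it adds no support. Of all probe sets, 12.4% lay lower in this way and 14.8% higher. The probe sets of sid-3, Y43F8C.13, R12C12.5, ZK1290.11 and ZK550.6 have names that do not mark them as specific to 1 gene. The remaining calls were probe sets of rab-7 and grl-20 that are not the brightest of their gene, and 2 without a gene name. Of these, rab-7 is named after its values were seen. For cyp-35A2, sid-3, Y43F8C.13 and F15D4.5, a fraction of 1 genotype had no present call, so the ratio there is only a bound. The changes given for cyp-35A2, Y43F8C.13 and F15D4.5 are therefore upper limits of the size. Detection was partial for others. Both iscu-1 and srbc-1 were called present on 1 of 3 nonpolysomal wild-type arrays, so their wild-type shares rest on a mostly undetected signal. For lgc-21 the same held for nonpolysomal mutant RNA, with 1 of 3. In the mutant, srbc-1 was called present on 2 of 3 arrays in each fraction. Combined abundance also changed for 8 of the 13 genes, 3 of them higher and 5 lower.

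These calls were few, and the count depended on the setting. With the set number as a replicate block 0 probe sets were called, although 2469 had an unadjusted p under 0.05 in limma, against 2730 without the block. Leaving out any single culture left 0 or 1, and leaving out any set left 0, with 1378 to 3459 at an unadjusted p under 0.05. Restricting the test to probe sets above the median signal gave 348 higher and 220 lower, and adding 50 to each signal gave 260 higher and 349 lower. Scaling on the bacterial control probe sets gave 10 higher and 342 lower, with the median of all probe sets at -0.47 in place of 0.03. Unadjusted p-values under 0.05 were 1381 for higher and 1349 for lower association, where about 667 in all were expected by chance. A count without a variance model asked in how many probe sets the polysomal shares of the genotypes did not overlap. All 3 mutant shares lay below all 3 wild-type shares for 1656 probe sets, or 12.4%, and above them for 1967, or 14.8%. Chance gives 5% in each direction, or 10% together.

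The mRNAs reported earlier, by other methods, to be translated less well without IFE-1 were examined as a fixed list of 4. Polysomal shares averaged 30.4% ± 8.87 in wild type and 40.6% ± 1.38 in the mutant for oma-1, 35.3% ± 3.51 and 43.5% ± 4.76 for pos-1, 41% ± 15 and 44% ± 4.2 for mex-1, and 21.3% ± 2.2 and 29.2% ± 4.60 for pal-1 (SD, n = 3). For mex-1 the wild-type culture of set 2 stood at 58.2%, above the mutant cultures, and the others at 33.7% and 31%. No member passed in limma, over all probe sets or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The list as a whole did not pass (median change 0.55; camera adjusted p = 0.134). Its median was higher in the mutant, which is not the direction that poorer translation without IFE-1 would give. The list passed as higher without the wild-type culture of set 2 (median 0.72, adjusted p = 0.00562) and without that set (0.84, adjusted p = 0.00689). All 4 are also in the maternal list, and of the 10 germline mRNAs of the comparison list 5 are in another list. The comparison list had a median change of 0.53 (adjusted p = 0.0105; adjusted p = 0.738 with an estimated correlation). Scaled on the bacterial controls, where the median of all genes was -0.46, it did not pass (median -0.01, or 0.45 relative to all genes, adjusted p = 0.0538), nor with signals as deposited (0.56, adjusted p = 0.054) or without set 3 (0.46, adjusted p = 0.1). Over all probe sets 0 of its members passed, and 4 were higher adjusted over the list alone. Its members with the smallest p were gld-1 (27% and 39% polysomal in wild type and mutant), fbf-1 (31.5% and 42.4%), fem-3 (22.1% and 34.9%) and fbf-2 (35.7% and 53.5%).

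Of the 24 fixed lists, 5 passed as higher and 2 as lower in association (camera with its preset correlation). None held with an estimated correlation, where the smallest adjusted p = 0.738, and limma's fry called 2 lists, major sperm proteins and elongation factors. Without set 2, whose wild-type culture stood apart from the others, 12 lists passed, and without that culture alone 11 passed. No list member passed the test over all probe sets, so member values are given as values. Major sperm proteins, the main cytoskeletal proteins of sperm, had the largest median change with quantile normalization, -0.79 (adjusted p = 4.84e-15; adjusted p = 0.738 with an estimated correlation). Their mean polysomal share was 62.3% ± 1.97 in wild type and 48.6% ± 2.58 in the mutant (SD, n = 3), and 20 of 23 were lower adjusted over the list alone. With signals as deposited the median was -0.51, and cuticle collagens (0.66) and proteasome (-0.61) changed more. The same held with median scaling (0.60 and -0.67 against -0.58). On the bacterial controls proteasome changed more (-1.18 against -1.09). None of the 23 probe sets of this family has a name that marks it as specific to 1 gene, although the annotation gives 1 gene for each. No probe sequences were at hand to test for signal shared between near-identical genes. For msp-64 the shares were 66% and 44%, and for msp-3 they were 61.0% and 42.2%. Proteasome subunits had a median change of -0.51 (adjusted p = 4.17e-09; adjusted p = 0.738 with an estimated correlation). Their share was 58.2% ± 1.72 against 49.5% ± 2.87, and 9 of 32 were lower adjusted over the list alone. Scaled on the bacterial controls the median was -1.18, or -0.72 relative to all genes. The shares of pas-4 were 72.8% and 52.4%, those of pas-7 57.3% and 38.3%, and those of pbs-2 69.0% and 50.5%. Intestinal genes had a median change of 0.40 (adjusted p = 0.000147; adjusted p = 0.738 with an estimated correlation), with 5 of 29 higher adjusted over the list alone. Scaled on the bacterial controls the list passed as higher, with a median of -0.06, or 0.40 relative to all genes (adjusted p = 5.09e-05), and without the wild-type culture of set 2 it was 0.26. Among them, cpr-6, a cathepsin B-like protease gene, had shares of 55.9% and 73.4%, and the metallothionein gene mtl-1 had 75.8% and 87.8%. Cuticle collagens had a median change of 0.39 (adjusted p = 2.58e-07; adjusted p = 0.765 with an estimated correlation), with 0 of 111 passing adjusted over the list alone and 39 higher and 1 lower at an unadjusted p under 0.05 in limma. Their median was 0.25 without the wild-type culture of set 2, and 0.66, 0.60 and 0.09 with signals as deposited, scaled to a common median and scaled on the bacterial controls. Maternal RNA-binding and cell-fate genes had 0.36 (adjusted p = 0.00102; adjusted p = 0.765 with an estimated correlation), and meiotic genes had 0.24 (adjusted p = 0.0494; adjusted p = 0.738 with an estimated correlation). In both, 0 members passed adjusted over the list alone, and 7 of 30 and 6 of 31 had an unadjusted p under 0.05 in limma. Scaled on the bacterial controls, which put the median of all probe sets at -0.47, neither list passed (medians -0.23 and -0.39, or 0.23 and 0.08 relative to all genes, adjusted p = 0.0719 and 0.974). The maternal list did not pass without set 3 either (0.27, adjusted p = 0.0551), and its median was 0.65 without set 2. The meiotic list missed the threshold with signals as deposited (adjusted p = 0.816), with median scaling (0.829), without set 1 (0.124), without set 2 (0.0899) and without each single culture other than those of set 3 (0.0557 to 0.11).

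**Figure D1:**
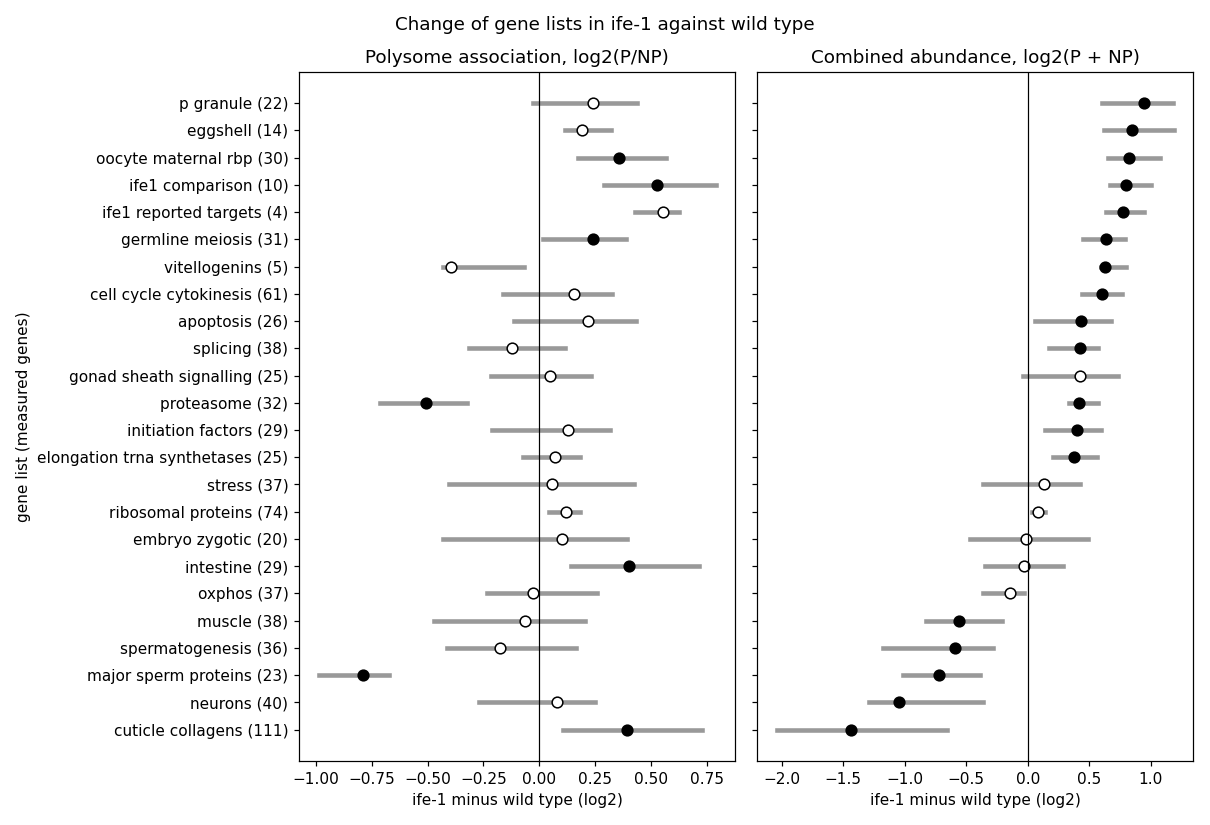
Median change of each fixed gene list in ife-1 against wild type on the log2 scale, for polysome association on the left and combined abundance on the right. Points are list medians, filled where the preset-correlation camera test gave an adjusted p under 0.05, bars span the quartiles of the members, the number of measured genes follows each name, and major sperm proteins lie at -0.79 and proteasome at -0.51 on the left, and cuticle collagens lie at -1.44 and neurons at -1.05 on the right.

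The other 17 lists did not pass in association. Median changes were 0.19 for eggshell genes, 0.24 for P granule genes, -0.18 for sperm genes outside the major sperm protein family, -0.40 for vitellogenins, -0.06 for muscle, 0.08 for neurons and 0.10 for embryonic patterning genes. They were 0.12 for ribosomal proteins, 0.13 for initiation factors, 0.07 for elongation factors and tRNA synthetases, -0.03 for oxidative phosphorylation and 0.16 for cell cycle genes. They were 0.22 for cell death, 0.06 for stress, 0.05 for somatic gonad signalling and -0.12 for splicing. For neurons, embryonic patterning, initiation factors and stress, the median and the mean of the list differed in sign. Some of these lists passed under other settings. Ribosomal proteins passed as higher with signals as deposited (0.39, adjusted p = 1.93e-07), with median scaling (0.33, adjusted p = 7.86e-07) and without set 2 (0.19, adjusted p = 0.00689) or its wild-type culture (0.16, adjusted p = 0.00562), and on the bacterial controls (adjusted p = 0.00164), where their median of -0.18 lay 0.28 above that of all genes. Splicing genes passed as lower with signals as deposited, median scaling and bacterial controls (-0.10, -0.16 and -0.67, adjusted p = 0.00441, 0.00353 and 0.005) and without the wild-type culture of set 3 (-0.14, adjusted p = 0.0314). Without the wild-type culture of set 2, eggshell (0.43, adjusted p = 0.00472), cell cycle (0.27, adjusted p = 0.0139) and cell death genes (0.22, adjusted p = 0.0435) passed as higher. Without the whole set they did so too (0.45, 0.28 and 0.33, adjusted p = 0.0124, 0.00899 and 0.0204), and oxidative phosphorylation passed as lower (-0.10, adjusted p = 0.0489). Adjusted over the list alone, calls were 2 higher in eggshell genes, 2 higher and 1 lower in sperm genes, 1 lower in muscle, 2 lower in initiation factors (ife-1 and ife-4), 1 lower in P granule genes (ife-1), and 4 higher and 4 lower in stress genes. The ratio of ife-1 is one of background signals in the mutant, where no array called it present, so it is not counted as a change. The wild-type ratio of ife-4 is only a bound, as for sid-3, since no nonpolysomal wild-type array called it present. Its fall passed adjusted over the list alone but not over all probe sets. Single members with low unadjusted p that missed the threshold included the superoxide dismutase genes sod-3 (84.8% and 67.1% in wild type and mutant) and sod-2 (76.0% and 54.3%). The muscle gene pat-4 had shares of 80.0% and 59.2% (adjusted p = 0.0531).

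RNA quality measures were compared between the groups without a test. The log2 ratio of 3′ to 5′ control signal for Gapdh was 2.00 ± 0.31 in wild-type nonpolysomal RNA and 1.27 ± 0.13 in wild-type polysomal RNA (SD, n = 3). In the mutant the corresponding values were 1.78 ± 0.59 and 2.02 ± 0.13. For actin they were 3.79 ± 0.66, 2.79 ± 0.24, 3.37 ± 0.99 and 3.18 ± 0.55 in the same order, and for ubiquitin 4.85 ± 0.28, 5.03 ± 0.14, 4.40 ± 0.52 and 4.41 ± 0.40. The bacterial control probe sets averaged 10.53 ± 0.18 on the log2 scale in wild-type nonpolysomal RNA, against 9.98 ± 0.08, 9.94 ± 0.50 and 9.96 ± 0.11 in wild-type polysomal, mutant nonpolysomal and mutant polysomal RNA.

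**Figure D2:**
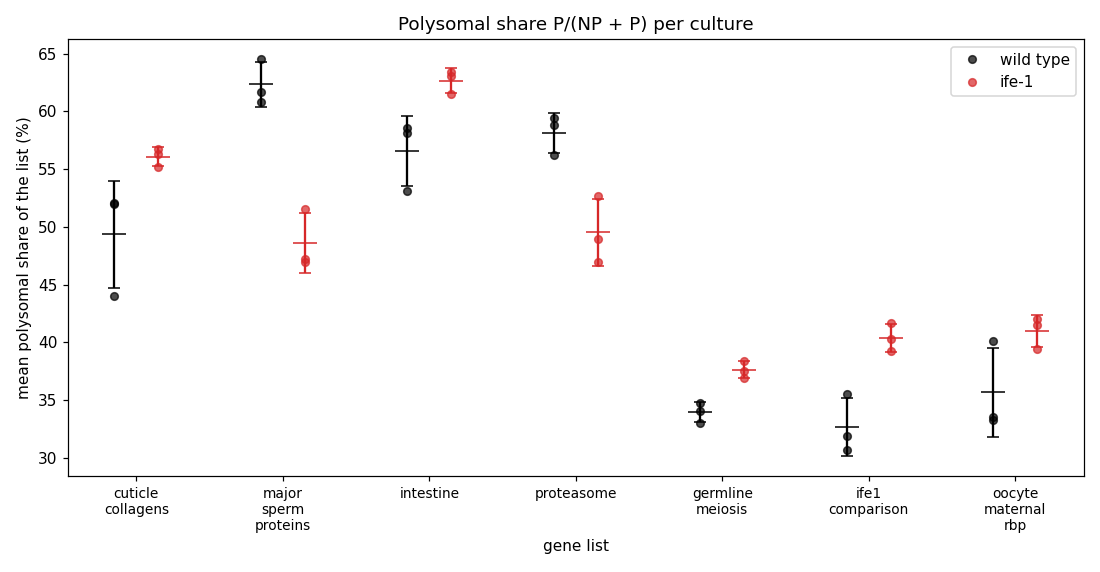
Mean polysomal share, in percent of the summed signal, of the 7 lists that passed the preset-correlation test in association. Each point is 1 culture, with 3 wild-type cultures in black and 3 ife-1 cultures in red, the bars give the mean ± SD, and major sperm proteins averaged 62.3% in wild type and 48.6% in the mutant, and proteasome genes averaged 58.2% and 49.5%.

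Combined abundance, the sum of both fractions, differed for many more mRNAs. In the mutant 2804 probe sets were higher and 2470 lower (limma, adjusted p under 0.05), of which 775 and 1180 differed at least 2-fold. Of the 8 genes named for the largest decreases, 4 encode cuticle collagens. The collagen mRNAs col-84, col-35 and col-102 were at least 80.6-fold, 45.4-fold and 57.1-fold lower, and none was called present on a mutant array. The mRNA of col-2 fell by 5.14 ± 0.47 on the log2 scale (SE, adjusted p = 0.000845). The ground-like genes grl-23 and grl-20 fell by 5.86 ± 0.79 and by 5.43 ± 0.47 (adjusted p = 0.00199 and 0.000757). B0554.1 was at least 21.8-fold lower. Among increases, C38D9.2 was at least 50.7-fold higher and was called present on no wild-type array (adjusted p = 1.86e-05). T22B7.7 was higher by 3.75 ± 0.31, F15D4.5 by 3.28 ± 0.23, nspe-7 by 3.15 ± 0.22 and the beta-tubulin gene tbb-6 by 2.55 ± 0.22. For F15D4.5 no wild-type polysomal array gave a present call, so its wild-type sum holds a bound. The scramblase-family gene scrm-4 and the infection response gene irg-2 were both higher by 2.52, and cdk-11.2 by 2.46. Scaling on the bacterial control probe sets gave 3645 higher and 1353 lower, with the median of all probe sets at 0.27 in place of 0.06. Without set 1 there were 659 calls and without set 3 there were 1649. Without the mutant culture of set 1 there were 2643, and without that of set 3 there were 3000.

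By list, 13 passed as higher in abundance and 5 as lower. None held with an estimated correlation, where the smallest adjusted p = 0.149, and fry called 18, without the lists of major sperm proteins and other sperm genes. Of 30 maternal RNA-binding and cell-fate genes, 26 were higher and 0 lower (median 0.83; adjusted p = 3.38e-08; adjusted p = 0.149 with an estimated correlation), 27 adjusted over the list alone. They included oma-2 (1.32 ± 0.20), mex-5 (1.06 ± 0.15) and nos-2 (1.15 ± 0.20). Eggshell genes had 11 of 14 higher (median 0.85; adjusted p = 0.000133; adjusted p = 0.149 with an estimated correlation), 12 adjusted over the list alone, among them the chitin synthase gene chs-1 (1.69 ± 0.19) and cbd-1 (1.19 ± 0.16). Of 22 P granule genes, 17 were higher and 1, ife-1 itself, was lower (median 0.94; adjusted p = 4.76e-05; adjusted p = 0.149 with an estimated correlation), and 18 were higher adjusted over the list alone. Within it pgl-1 was higher by 1.67 ± 0.27 and prg-1, a Piwi protein gene, by 1.19 ± 0.20. Meiotic genes had 19 of 31 higher (median 0.64; adjusted p = 9.64e-07; adjusted p = 0.149 with an estimated correlation), 21 adjusted over the list alone, such as him-6 and coh-3. Cell cycle genes had 36 of 61 higher (median 0.60; adjusted p = 5.24e-10; adjusted p = 0.149 with an estimated correlation), 40 adjusted over the list alone, including mcm-3 and spd-2. All 5 vitellogenins were higher (median 0.63; adjusted p = 0.00571; adjusted p = 0.149 with an estimated correlation), also adjusted over the list alone. All 4 earlier reported IFE-1 mRNAs were higher, also adjusted over the list alone, oma-1 by 1.04 ± 0.27, mex-1 by 0.91 ± 0.20, pal-1 by 0.64 ± 0.17 and pos-1 by 0.63 ± 0.18 (median 0.78; adjusted p = 0.022; adjusted p = 0.149 with an estimated correlation). In the comparison list 8 of 10 were higher (median 0.80; adjusted p = 0.00026; adjusted p = 0.149 with an estimated correlation), 10 adjusted over the list alone. Splicing (11 of 38 higher, median 0.43), proteasome (9 of 32, 0.42), elongation and tRNA synthetases (10 of 25, 0.38) and initiation factors (9 of 29 higher and 2 lower, 0.40) had adjusted p of 0.000133, 4.76e-05, 0.000624 and 0.00704. With an estimated correlation their adjusted p was 0.149, 0.414, 0.149 and 0.238. Adjusted over the list alone, 11, 9, 10 and 7 were higher, and 1 initiation factor was lower. Cell death genes had 6 of 26 higher and 1 lower (median 0.43; adjusted p = 0.0114; adjusted p = 0.149 with an estimated correlation), the same counts adjusted over the list alone, and ced-3, a caspase gene, was higher by 1.65 ± 0.22. Scaled on the bacterial controls, the median of all genes was 0.24 and list medians moved up. They were 1.28 for maternal, 1.07 for meiotic, 0.99 for cell cycle and 0.74 for cell death genes. For splicing, proteasome, elongation and initiation factors they were 0.83, 0.70, 0.65 and 0.70, and for other sperm genes -0.33.

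Collagen, neuron, muscle and sperm lists passed as lower. Of 111 cuticle collagens 79 were lower and 1 higher (median -1.44; adjusted p = 2.32e-18; adjusted p = 0.149 with an estimated correlation), 84 lower and 3 higher adjusted over the list alone. Setting the 5 collagens with bounds to their bounds left the median at -1.44, but a median does not move while such members stay on the same side of it. Of 40 neuronal genes 27 were lower and 0 higher (median -1.05; adjusted p = 3.27e-09; adjusted p = 0.149 with an estimated correlation), also 27 adjusted over the list alone. The neuropeptide genes flp-9 and flp-5 fell by 1.47 ± 0.14 and by 1.43 ± 0.15. Of 38 muscle genes 21 were lower and 0 higher (median -0.56; adjusted p = 4.95e-06; adjusted p = 0.149 with an estimated correlation), also 21 adjusted over the list alone, with the troponin gene tnc-2 falling by 1.65 ± 0.14. Major sperm proteins had a median of -0.72 (adjusted p = 0.00413; adjusted p = 0.646 with an estimated correlation), and 0 of 23 passed in limma, over all probe sets or adjusted over the list alone, with 3 at an unadjusted p under 0.05. Other sperm genes had a median of -0.59 (adjusted p = 0.0299; adjusted p = 0.728 with an estimated correlation), with 3 of 36 lower and 1 higher, and 1 lower adjusted over the list alone. Mean log2 signals of major sperm proteins were 14.90, 13.47 and 14.79 in wild-type cultures 1 to 3 and 13.58, 13.79 and 13.64 in the mutant, so that the wild-type culture of set 2 lay below the mutant cultures. It also did so for the other sperm genes, at 9.10 against 9.54 to 9.70. Without it the medians were -1.20 and -1.41 (adjusted p = 1.01e-09 and 9e-10). Without set 1 they were -0.43 and -0.27 (adjusted p = 0.08 and 0.186), and without set 3 they were -0.42 and -0.24 (adjusted p = 0.0564 and 0.357). Other sperm genes missed the threshold without the wild-type culture of set 1 or 3 or the mutant culture of set 2 (adjusted p = 0.205, 0.309 and 0.0866), and major sperm proteins had a median of -0.43 without the first. Intestinal genes had 4 of 29 higher and 5 lower (median -0.03; adjusted p = 0.667), and 1 higher and 4 lower adjusted over the list alone. Their median was -0.30 with signals as deposited and -0.33 with median scaling (camera adjusted p = 0.136 and 0.105). The lists of embryonic patterning (median -0.01), ribosomal proteins (0.09), oxidative phosphorylation (-0.14), stress (0.13) and somatic gonad signalling (0.42) did not pass with quantile normalization, and the medians of patterning and stress genes differed in sign from their means. Adjusted over the list alone, the numbers higher in these lists were 2, 0, 1, 7 and 8, and those lower were 5, 0, 3, 9 and 2. Oxidative phosphorylation, at an adjusted p = 0.0501, passed as lower with signals as deposited and with median scaling (-0.37 and -0.38, adjusted p = 0.00352 and 0.00362). It also passed with fry (adjusted p = 0.0183) and without set 1, its wild-type culture or its mutant culture (adjusted p = 0.0345, 0.0373 and 0.0362). Somatic gonad signalling passed as higher with signals as deposited, median scaling and fry (adjusted p = 0.0412, 0.044 and 0.0307) and without set 2 or its mutant culture (0.57 and 0.49, adjusted p = 0.0272 and 0.0383). Ribosomal proteins changed sign with the scaling, at -0.26 with signals as deposited (adjusted p = 0.000365) and -0.28 with arrays scaled to a common median (adjusted p = 0.000307).

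The authors' deposited table gives a mean fold of the polysomal share as wild type over ife-1, the opposite direction to the differences above. Its highest values among the named genes, with the authors' SD, were 3.43 ± 3.98 for fbxb-40, 3.24 ± 4.09 for M116.2, 2.63 ± 2.41 for C23F12.4, 2.2 ± 1.80 for clec-101 and 2.2 ± 0.0992 for F25H9.2. The SD exceeded the mean for fbxb-40 and M116.2. No array of the mutant gave a present call for clec-101, and no wild-type array gave one for F25H9.2. Its lowest were 0.377 ± 0.291 for bath-19, 0.391 ± 0.0760 for gpa-9, 0.417 ± 0.196 for F14H3.5, 0.449 ± 0.0713 for ZK1290.11 and 0.452 ± 0.278 for scl-15. A mean fold of at least 1.5 was deposited for 96 probe sets, of which 8 kept it after the SD was subtracted. For 179 probe sets the fold was as large the other way. Of the 96, 87 had lower association in the mutant at an unadjusted p under 0.05 in limma. Of the 10 genes just named, ZK1290.11 alone passed the test over all probe sets here.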

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

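The tests of the abundance pattern and of the dim probe sets were chosen after those results were seen. The others were set down before, although the first pattern is named after lists that passed as lower in the same data.

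The polysomal against nonpolysomal contrast differed between the genotypes, by the test of the difference itself, for 13 genes. The differences (ife-1 minus wild type, log2) were -2.49 for iscu-1, -2.44 for Y43F8C.13, -2.27 for srbc-1, -1.97 for elo-4, -1.76 for K06H6.1, -1.63 for sid-3, -1.61 for F15D4.5, -1.58 for R12C12.5 and -1.58 for lgc-21. They were 2.07 for cyp-35A2, 1.99 for ZK1290.11, 1.73 for T12D8.5 and 1.70 for ZK550.6. Those of cyp-35A2, Y43F8C.13 and F15D4.5 are upper limits of the size, since a fraction had no present call. Those of iscu-1, srbc-1 and lgc-21 rest in part on a fraction called present on 1 of 3 arrays. With the growth set as a block, which pairs the genotypes, none of the 13 passed (limma adjusted p from 0.123 to 0.132). By camera with a preset correlation, the same contrast differed for 7 lists (adjusted p of 0.738 or more with an estimated correlation), with medians of -0.79 for major sperm proteins, -0.51 for proteasome, 0.53 for the comparison list, 0.40 for intestine, 0.39 for cuticle collagens, 0.36 for maternal genes and 0.24 for meiotic genes.

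The first pattern is lower association of major sperm protein and proteasome mRNAs. Compression of bright signals would put the medians among those of random lists matched on mean signal. Of 10000 such lists, 0% lay as low as major sperm proteins, and 0% as low as proteasome. Random members were drawn independently, while members of the 2 real lists correlated at 0.37 and 0.33. The random medians therefore spread too little, and the 0% cannot exclude compression. They centred on 0.19 and 0.20, so equally bright genes did not fall as a group. Scaling would bring the medians of the 2 real lists near that of all genes. Yet over 5 scalings they stayed at -0.63 and -0.55 or lower relative to it. Of these scalings, 3 use 1 factor per array and give the same relative value by construction. Signal shared among near-identical sperm genes stays open, since 0 of the 23 members have a probe set whose name marks it as specific to 1 gene. The lower association may follow the genotype, but 2 of the 10 splits of the cultures, the real one with 7 lists included, called as many, and the other called 11.

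The second pattern is higher abundance of maternal, eggshell, P granule and meiotic lists with lower abundance of collagen, neuron and muscle lists; it leaves out the sperm lists, which were lower, and the vitellogenins, made in the intestine, which were higher. A lower share of all somatic tissue alike would lower intestine with the rest. With quantile normalization the intestine median was -0.0322 (95% bootstrap interval -0.23 to 0.26), above muscle (-0.71 to -0.40) and neurons (-1.17 to -0.74). The bootstrap resampled the genes of each list, with the change of each gene held fixed. Its intervals therefore give the spread among genes, taken as independent, and not the variation between cultures. Relative to all genes, intestine lay lower with signals as deposited, median scaling and bacterial controls, at -0.24, -0.26 and -0.25. Muscle lay at -0.56, -0.55 and -0.62 there, and neurons at -0.94, -0.95 and -0.98. Intestine thus fell less than both in each scaling. Intervals were computed with quantile normalization only and leave out the variation between cultures, so a smaller fall of intestine stays open. Fewer larvae among the mutant worms could contribute, since the median of collagens, which are made around moults, minus that of muscle and neurons together was -0.73. The labels give mixed stages for both genotypes and no composition, which keeps this open. A direct effect of the genotype was not tested apart from these.

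The third pattern is the small number of association calls over all probe sets beside the larger number over brighter ones. Noise of dim probe sets may account for part of it: the median SE was 1.22 times larger below the median signal (0.28 against 0.23), between the bounds set for and against this explanation. This stays open.

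Splits of the 6 cultures into 3 and 3 are 10, too few for a share under 0.05. The real split gave 17 association calls, 5274 abundance calls, 18 abundance lists and 3623 probe sets without overlap. The highest other split gave 0, 0, 15 and 1983, and 1 split, the real one, was as large in each. Among the 4 splits that part all 3 growth sets, the highest others were 0, 0, 13 and 1983. Exchanging fractions within cultures gives 4 arrangements, also too few. The real one gave 7438 calls in wild type and 6517 in the mutant, the highest other gave 0 and 0, and 1 of 4 was as large.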

How the results depend on the processing

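Bacterial control scaling, probe sets present on all 12 arrays and the omission of single cultures were chosen after seeing the data. The count of 17 association calls was 9 with signals as deposited, 352 scaled on the bacterial controls, 609 with an offset of 50, 568 above the median signal, 348 for probe sets present on all 12 arrays, 6 from the interaction without culture block and 53 from untransformed shares. It was 0 with the replicate block, and 0 to 1 without each set or culture. The calls differ as well: of the 568, 3 were among the 17. Above the median signal the other counts were 3236 for abundance, 4372 and 4100 for the fractions in wild type and mutant, and 2193 for shares without overlap, where fewer probe sets were tested. Leaving out sets or cultures gave 659 to 6503 abundance calls, 4857 to 7208 and 4018 to 5778 fraction calls, and 5 to 12 association lists, with 12 without set 2 and 11 without its wild-type culture. With estimated correlations 0 association and 0 abundance lists passed, and fry called 2 association lists. Scaling on the bacterial controls moved all genes together, from a median of 0.05 to -0.46 in association, and by this shift the medians of lists fell below 0, at -0.012 for the comparison list, -0.23 for maternal, -0.39 for meiotic and -0.065 for intestinal genes and -0.18 for ribosomal proteins. Relative to all genes these lists lay at 0.45, 0.23, 0.08, 0.40 and 0.28. By construction these are the values with signals as deposited, since 1 factor per array moves all genes alike. Ribosomal proteins in abundance were at -0.26 as deposited and -0.28 with median scaling. The cause was not tested except where stated. With the replicate block, abundance calls were 4797 and list counts stayed at 7 and 18. Unpaired fractions (no replicate block) gave 5693 and 4779 calls. Where they were run, median scaling (on 6 counts and the shares without overlap), quantile within fractions and the variance trend (on the 4 gene counts) kept the totals within 1.5 times, though not each direction: association calls went from 4 higher and 13 lower to 4 and 8 with median scaling and to 2 and 10 with the trend. Apart from the 39 control probe sets, the value table holds the probe sets tested and no others, so that alternative has no value. Of the values of named genes under the alternatives, 3687 kept direction and side of the threshold, 310 lost it, 157 gained it and 0 reversed. Of the list values these were 588, 51, 29 and 7, of which the 5 on the bacterial controls follow from the common shift. Values called in neither fit count as kept, and all outcomes are pooled. Of the 17 association calls, 0 were called again with the replicate block or without any set or single culture. Sign changes of uncalled values, 43 for genes and 45 for lists, are not counted as reversed. Signal over background limits the ratios: 4.11% of probe sets in wild type and 5.06% in the mutant had no present call in the nonpolysomal fraction.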

Other observations

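By chromosome, the median abundance change (ife-1 minus wild type, log2) was -0.24 for 1414 genes on X, 0.17 for 1734 on I, 0.16 for 1636 on III, 0.04 for 1793 on II and for 1736 on IV, and -0.05 for 1996 on V. On X 29.4% of genes were lower and 10.9% higher, and on I 13.9% were lower and 26.3% higher. Median association changes lay between 0.03 and 0.06 on every chromosome. These values were looked at after the other results, and no explanation was tested.

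Across probe sets, which are not independent replicates, the changes in association and in abundance correlated at r = 0.014. The genotypes' mean log2 ratios of polysomal to nonpolysomal signal correlated at r = 0.83.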
